A study of Arabidopsis thaliana with 4 samples.

How the data were processed

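RNA sequencing of Arabidopsis thaliana leaves was used to measure transcript levels in local leaves, to which water or Dox was given, and in systemic leaves of the same 2 sets of plants. Dox was given to local tissue at 25 um/g, per the labels, which do not spell the name out. The labels give no treatment for the systemic leaves themselves. The plants were raised on an agar medium with sucrose under long days. Per the labels' protocols, mRNA was purified with a TruSeq RNA Sample Prep kit and libraries were made with a SMARTER mRNA-Seq kit. The hour of harvest, the time between treatment and harvest and the strand setting are not given in the sources used here.

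The values are whole-number read counts per gene, as the authors deposited them, with no normalization. The submitters' processing notes name Trimmomatic 0.39, FastQC 0.11.9, HISAT2, featureCounts 1.6.3 and DESeq2, without saying what each did or in which order. The genome build, the annotation and the handling of reads that map to several genes are not given in the sources used here. Reads of near-identical genes (CAB1, CAB2 and CAB3, the RBCS1B, RBCS2B and RBCS3B group, HSP70 genes, copies of ribosomal protein genes) may therefore be divided between copies by the counting, and reads of overlapping or antisense genes cannot be told apart. The counts cover 32982 genes, of which 149 are transcripts outside the numbered loci that take 0.278% to 0.604% of the counts of a library. Of the others, 32548 matched a locus of the TAIR10.1 assembly by identifier and 285 did not. That assembly supplied names, gene types and transcript lengths, and no coordinates are given.

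Each group holds 3 columns of counts, 12 in all. Columns of one group differed far beyond counting noise, with a median chi-square per degree of freedom over genes of 18.4 in control local, 19.0 in control systemic, 24.0 in Dox local and 10.4 in Dox systemic leaves. They were therefore treated as 3 libraries per group. Nothing says whether they came from separate plants, so p-values measure only the spread between these libraries, which may be technical. The design fixed before the data were examined took each group as 1 library and allowed no test within a leaf position. Its counts of genes at least 2-fold apart were kept as written, on counts summed over the 3 libraries of a group, with a prior count of 2 and among genes at 1 CPM or more in either group. Every test of 3 libraries against 3 was added once the columns had been seen.

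The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on 4 group means over 12 libraries, with TMM normalization and the filterByExpr filter at a minimum count of 10. It left 19403 genes, 8 residual degrees of freedom, 3.32 prior degrees of freedom and a common biological coefficient of variation of 0.32. P-values were adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. The contrasts planned in outline were 4: Dox over control in local leaves, Dox over control in systemic leaves, systemic over local among control plants, and the Dox difference common to both positions. Systemic over local among Dox plants and the interaction (local minus systemic Dox difference) were added. DESeq2 1.42.0 and limma 3.58.1 were run as alternatives.

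The gene lists fixed in advance number 32. They cover mitochondrial stress, mitochondrial chaperones and proteases, the nuclear-encoded respiratory chain, mitochondrial-encoded and plastid-encoded genes, nuclear photosynthesis, plastid and cytosolic ribosomal proteins, and hormone groups (salicylic acid and systemic acquired resistance, jasmonate, ethylene, abscisic acid and dehydration, auxin, cytokinin). They also cover stress groups (cytosolic and plastid heat shock, endoplasmic reticulum stress, reactive oxygen response, touch and cold, iron deficiency), senescence, anthocyanin and flavonoid, camalexin and indole glucosinolate, aliphatic glucosinolate, cell division, circadian clock and phase change genes, reference genes, and markers of root, flower, shoot apex, guard cell and vascular tissue. A list was tested when at least 3 members were measured, which left 30, with limma's camera at its preset correlation of 0.01, camera with a correlation estimated per list, and fry. Camera asks whether a list moved relative to all other genes. The p-value of fry asks whether its members moved one way on balance, and its mixed p-value whether they changed in either direction. The percentile of a list median came from 10000 random lists of the same size matched on mean expression.

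The genes to be named were set by a rule fixed in advance. For each Dox comparison it takes the 10 nuclear protein-coding genes with the highest and the 10 with the lowest log2 ratio among those at 10 CPM or more in either group, and up to 4 members per list at 1 CPM or more with the largest absolute log2 ratio. The rule was applied to the edgeR log2 fold change. Genes named outside it are said to have been chosen after their values were seen.

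Library numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means across genes. In the comparison of leaf positions among control plants the correlations were 0.291, 0.399 and 0.704, each library correlated best with its own number, and the numbers were taken to pair these libraries. The numbers come from the column names, and nothing else ties the libraries together. Between leaf positions among Dox plants, where the same pairing would be due, the correlations were -0.0998, -0.00816 and 0.000873. There no same-numbered libraries were each other's best match. The pairing among control plants was thus accepted from these data alone. In each comparison of Dox with control at least 1 correlation was under 0.1.

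Alternatives covered the normalization (DESeq2 size factors, upper-quartile factors, total counts alone), the low-count filter, the prior count, the fold threshold, thinning to equal depth, leaving out organelle-encoded genes before scaling, DESeq2, limma-trend, voom with library quality weights, fits over the 6 libraries compared, library number as a block, removal of each library's trend with transcript length, and leaving out each library in turn. A pair of libraries, control local 3 and Dox local 1, was also left out together, as they lie at one end of the first principal component. Before use the procedure was tested on counts simulated from the real means for 19201 genes. With 100 genes changed 2-fold and 100 changed 4-fold, the local comparison recovered 17% and 74% of them, and 8 of its 99 calls were false. The systemic comparison recovered 14% and 76%, and 2 of its 92 calls were false. Camera found a simulated list whose members were shifted and not one whose members were unshifted. The simulation drew each gene independently. Its figures therefore do not cover genes that move together, and say nothing of false list calls in these libraries.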

Results

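Transcript levels were measured in leaves of Arabidopsis thaliana in 4 groups of 3 libraries each: local leaves given water (control local), systemic leaves of those plants (control systemic), local leaves given Dox (Dox local) and systemic leaves of Dox-treated plants (Dox systemic). The series title presents Dox as a mitochondrial stress whose effect is followed from the treated to the untreated leaves. Total counts ranged from 18981328 to 21380652 per library, and 21429 to 22325 genes were detected in each, so depth was even. All log2 fold changes are from edgeR, and levels are means ± SD over 3 libraries of CPM, the count scaled to library size.

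The first principal component held 36.3% of the variance. It parted Dox local libraries (8.19 to 75.4) from Dox systemic libraries (-65.2 to -23.3), while control local (-27.5 to 76.3) and control systemic libraries (-53.3 to 37.9) spread over both sides. Control local library 3 (76.3), Dox local libraries 1 (75.4) and 3 (43.9) and control systemic library 3 (37.9) lay at one end, where the leading genes included the heat shock factor HSFA2, HSP70, the abscisic acid phosphatase HAI1 and the cell wall enzyme XTH18. Dox systemic library 1 (-65.2) and control systemic library 2 (-53.3) lay at the other, which was led by auxin-induced genes such as IAA29, GH3.3 and SAUR19. Groups accounted for 36.9% of the variance against 27.3% by chance, and the median correlation was 0.951 between libraries of one group and 0.948 between libraries of different groups. Any comparison of groups therefore sets differences between conditions against large differences among libraries of one condition.

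**Figure D1:**
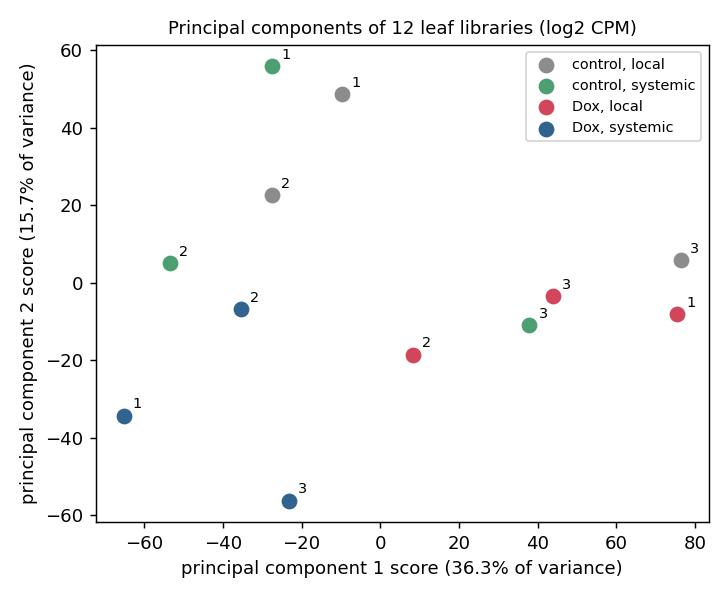
Position of the 12 libraries on the first (36.3% of variance) and second principal components of log2 CPM, each point a library and each colour a group. Dox local libraries lie to the right of Dox systemic libraries, and each control group is spread along the horizontal axis, control local from -27.5 to 76.3.

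In local leaves, the question was what Dox did where it was applied. Of the 10 highest genes, 3 are on the heat shock list (HSFA2, MBF1C and HSP70). HSFA2 (AT2G26150), a heat shock transcription factor, was 34.4-fold higher with Dox (log2 5.11, SE 1.79; 39.2 ± 66.1 against 1.18 ± 1.8 CPM), and the transcriptional coactivator MBF1C (AT3G24500) was 10.7-fold higher (log2 3.42, SE 1.12). The chaperones HSP70 (AT3G12580; log2 3.15, SE 1.11), AT3G09440 (3.02) and Hsp70-2 (AT5G02490; 2.89) stood beside them, with HSP101, a disaggregase, at 2.45 (SE 0.75). A single library carried these values. HSFA2 stood at 116 CPM in Dox local library 1 and at 1.25 and 0.865 CPM in the others, and without library 1 the log2 fold change was -0.14 for HSFA2, 0.92 for MBF1C, 0.81 for HSP70, 0.40 for AT3G09440, 1.17 for Hsp70-2 and 0.48 for HSP101. HSFA2 stood at 8.04 without control local library 3. The J-domain protein genes AT3G14200 (log2 3.76, SE 0.98) and AT2G20560 (2.81) were also among the highest, and AT3G14200 and AT1G66080 (2.58, SE 0.69) were the 2 of the 10 highest whose Dox and control libraries did not overlap. In the absence of Dox local library 1, AT3G14200 stood at 1.47, AT1G66080 at 1.11 and AT2G20560 at 0.46. The 10 lowest genes were 4.38-fold to 9.11-fold lower. They included PYK10 (AT3G09260), a beta-glucosidase of endoplasmic reticulum bodies (7.52-fold lower, log2 -2.91, SE 0.95; 26.7 ± 12.8 CPM with Dox), the tandem zinc finger gene AT5G44260 (-3.03, SE 1.00), the jasmonate-inactivating sulfotransferase ST2A (-3.19, SE 1.48), the auxin gene IAA29 (-2.72, SE 1.51), the light-signalling factor HFR1 (-2.21, SE 0.77) and the brassinosteroid enzyme BR6OX2 (-2.13, SE 1.03). Control local library 3 lay below all 3 Dox libraries for IAA29 (1.78 CPM), BR6OX2 (1.42 CPM) and ST2A (0.356 CPM), and within their range for HFR1 (2.97 CPM). The log2 fold changes became -1.58 for IAA29, -1.86 for ST2A and -1.6 for BR6OX2 without control local library 2, -1.48 for HFR1 without control local library 1 and -4.51 for IAA29 without Dox local library 2. PYK10 is also the 1 of 10 root marker genes that was measured. Of the 10 lowest genes 3 had no overlap between groups: PYK10, AT5G44260 and AT3G55240 (-2.16, SE 0.66).

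By edgeR's quasi-likelihood test 0 of 19403 genes passed an adjusted p of 0.05 between Dox and control local leaves, the smallest adjusted p being 0.902. At an unadjusted p under 0.05 there were 915 genes, 4.72% of those tested where 5% are due by chance, and DESeq2 called 8 higher and 6 lower, none of them among the 131 genes named by rule. DESeq2 gave no adjusted p for HSFA2, AT3G14200, MBF1C and PR1, so it could not call them. All libraries of one group lay above all of the other for 7.54% of genes, where chance gives 10%. On summed counts, 328 genes were at least 2-fold higher and 327 at least 2-fold lower of 17979, a description with no test. Those counts became 218 higher without control local library 1, 1051 and 590 without control local library 3, and 563 and 637 without Dox local library 2.

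The mitochondrial stress list, nuclear genes raised by mitochondrial dysfunction, had 13 members higher and 8 lower in Dox local leaves. Its median log2 fold change was 0.07 (95% interval over members -0.15 to 0.43), and it did not pass (camera, adjusted p = 0.695). Single libraries moved that median across 0: it was -0.07 without control local library 2, 0.55 without control local library 3, and 0.18, 0.26 and -0.01 without Dox local libraries 1, 2 and 3. With total counts alone as the scaling, which moved the median of all genes from 0.017 to -0.119 in local and from -0.001 to 0.113 in systemic leaves, the list median was -0.06. Its largest members were AT5G51440, a mitochondrial small heat shock protein (log2 1.69, SE 1.17), AT5G09570 (1.35) and the transporter DTX1 (1.09), while ABCB4 was lower (-0.57). AOX1A, the alternative oxidase most used as a marker of mitochondrial retrograde signalling, was at 0.07 (SE 0.36); it lies outside the naming rule and is given because of its role. Its value was -0.01, -0.21 and 0.55 without control local libraries 1, 2 and 3, and -0.17, 0.17 and 0.19 without Dox local libraries 1, 2 and 3. Nuclear genes of the respiratory chain (median 0.10, 17 of 20 positive) and mitochondrial chaperones and proteases (0.04) did not pass, at adjusted p = 0.243 and 0.45, and under that scaling they stood at -0.05 and -0.06, above the median of all genes (-0.119).

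Of 30 lists, 7 passed camera at its preset correlation in local leaves. Every other division of these libraries into groups of 3 gave more, 10 to 13 lists. In this and every other comparison no list call held with an estimated correlation, and those p-values are given beside each call. Cytokinin response rose (median 1.17, 7 of 7 members positive, adjusted p = 0.000413), with the type A response regulators RR16 at log2 1.67 (SE 0.50; 12.8 ± 8.13 against 4.03 ± 0.727 CPM), RR5 at 1.19 and ARR7 at 1.17. Heat shock rose (1.25, 13 of 14, adjusted p = 0.000276), as did plastid ribosomal proteins (0.21, 16 of 16, 0.000413; PRPL28 0.49, SE 0.17), iron deficiency (0.51, 12 of 12, 0.00353) and plastid-encoded genes (0.23, 55 of 74, 0.00487). The plastid ribosomal median lay at percentile 72.42 of the random lists matched on expression, so it was not unusual for genes of that level. In the iron list, AT1G47400 and AT1G47395, which encode IRON MAN peptides, were at 1.75 (SE 0.73) and 1.63 (SE 0.56). Senescence (median -0.25, 10 of 13 negative, adjusted p = 0.0136) and mitochondrial-encoded genes (-0.45, 58 of 63 negative, 0.00132) fell. The dark-induced genes ASN1, an asparagine synthetase, and SEN1 (AT4G35770) were at -1.70 (SE 0.52) and -1.62 (SE 0.51). When camera ran on log2 CPM senescence was not called (adjusted p = 0.0698), and cytosolic ribosomal proteins (median 0.12) were (0.0231, against 0.0603 on counts). Each of the 7 had adjusted p = 0.886 with an estimated correlation, and fry called none of the 30. Adjusted over the list alone, 5 members of heat shock and 1 of cytokinin response passed, against 0 over all genes.

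The local list values depended on single libraries. Without control local library 1 the medians were 0.71 for cytokinin response, 0.24 for iron deficiency, 0.13 for plastid ribosomal proteins, 0.11 for plastid-encoded genes, -0.13 for senescence and -0.71 for mitochondrial-encoded genes, and 4 lists passed. Without control local library 2 they were 0.78 for heat shock, 0.90 for iron deficiency, 0.15 for plastid-encoded and -0.76 for mitochondrial-encoded genes. Without control local library 3, at one end of the first component, mitochondrial-encoded genes turned to 0.22, heat shock stood at 2.28, plastid-encoded genes at 0.44 and senescence at -0.15, and 11 lists passed. Without Dox local library 1, at the same end, heat shock stood at 0.18, iron deficiency at 0.87, plastid-encoded genes at 0.03 and senescence at -0.07. Without Dox local library 2, 13 lists passed, and without Dox local library 3 iron deficiency stood at 0.32. With control local library 3 and Dox local library 1 both left out, 12 lists passed and the mitochondrial-encoded median was 0.31.

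In systemic leaves, the question was what differed in leaves that had received no Dox themselves. The cytokinin response regulator RR16 (AT2G40670) was 6.18-fold higher in systemic leaves of Dox plants (log2 2.63, SE 0.50; 44.7 ± 12.1 against 7.22 ± 3.55 CPM), the triterpene synthase LUP1 (AT1G78970) 9.09-fold (3.18, SE 0.79; 75.0 ± 59.9 against 8.27 ± 2.99 CPM), and the cell wall expansins EXP3 and EXPA8 were at log2 2.44 (SE 0.50) and 2.43 (SE 0.71). CAB2 (AT1G29920), a gene for a light-harvesting protein, was 12.6-fold lower (log2 -3.65, SE 0.93, 21.6 ± 2.94 against 272 ± 215 CPM). Its value may be affected by how the counting divided reads with the near-identical CAB1 and CAB3. LHCB2.1 was 5.47-fold lower (-2.45, SE 0.69, 10.5 ± 2.22 against 57.8 ± 11.9 CPM) and LHCB6 2.32-fold (-1.22, SE 0.30, 429 ± 89.6 against 996 ± 198 CPM). The alternative oxidase AOX1D (AT1G32350) was lower in all 3 Dox libraries (log2 -5.20, SE 1.35), at 0.0904 ± 0.0463 against 3.54 ± 5.01 CPM; only 6 reads in the Dox group against 207 lie behind it, for a log2 ratio of summed counts of -5.23 (95% interval -6.69 to -4.08, counting error only). Other low genes were the glutaredoxin GRXS13 (-2.90), DIN10, induced by darkness and sugar starvation (-1.63, SE 0.36), and the clock gene PRR7 (-2.32, SE 0.64; 10.7 ± 6.64 against 53.5 ± 11.2 CPM). Of the 10 highest genes 8 had no overlap between groups, and of the 10 lowest 5.

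Several of the lowest genes rested on control systemic library 1. ARD3, a dioxygenase of methionine salvage, was at log2 -4.51 (SE 2.01) and the immune gene AIG1 at -3.90 (SE 1.63). Without control systemic library 1 they were at 2.56 and 0.68, PAD3, the last enzyme of camalexin synthesis, moved from -2.86 to -0.52, TAT3 from -3.01 to -0.26, GSTU4 from -3.15 to -1.21, GRXS13 from -2.90 to -1.64 and AOX1D to -2.76. The values of CAB2 (-2.90), LHCB2.1 (-2.29), LHCB6 (-1.03), RR16 (2.30), DIN10 (lowest and highest without any library -2.22 and -1.34) and PRR7 (-2.16 without control systemic library 1) stayed on the same side of 0. SLAH3, an anion channel, went from -2.92 to -1.08 without control systemic library 3, and without Dox systemic library 1 the auxin repressor gene IAA5 went from 2.78 to 1.12, DFL1 from 2.39 to 1.05 and EXPA8 from 2.43 to 1.57.

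By edgeR 0 of 19403 genes passed an adjusted p of 0.05 in systemic leaves, the smallest adjusted p being 0.451. At an unadjusted p under 0.05 there were 1670 genes (8.61% where 5% are due), and DESeq2 called 59 higher and 63 lower. Of the 134 genes named by rule, DESeq2 called 6 higher (LUP1, RR16, AT5G44350, EXP3, EXPA8 and AT3G12710) and 9 lower (CAB2, LHCB2.1, LHCB6, AOX1D, DTX1, GRXS13, AT5G03350, DIN10 and PRR7), with DESeq2 adjusted p from 0.000998 for RR16 to 0.0469 for EXPA8. Libraries of the groups did not overlap for 16.4% of genes, against 10% by chance. On summed counts 409 genes were at least 2-fold higher and 643 at least 2-fold lower of 18148; without control systemic library 3 the higher count was 642.

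The mitochondrial stress list fell in systemic leaves: 15 of 21 members were negative, 9 of them at least 2-fold. The list had a median of -0.60 (95% interval over members -1.89 to 0.01) and a camera adjusted p = 7.9e-06. Its adjusted p = 0.241 with an estimated correlation, and fry gave 0.156 one way and 0.0491 for change in either direction. Over all genes 0 members passed, and 4 did adjusted over the list alone. Beside AOX1D the lowest were the transporter DTX1 (log2 -3.13, SE 0.84), the mitochondrial small heat shock protein AT5G51440 (-2.75, SE 1.33) and the glucosyltransferase UGT74E2 (-2.66, SE 1.16). AOX1A was at -0.42 (SE 0.36). The median lay between -0.89 and -0.55 whichever library was left out. Mitochondrial chaperones and proteases (median -0.08, adjusted p = 0.283) and the nuclear-encoded respiratory chain (0.03, 0.714) did not pass, and CPN10, a mitochondrial chaperonin, was at -0.77.

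Nuclear photosynthesis genes fell more uniformly: 27 of 29 were negative, with a median of -0.64 (95% interval over members -0.86 to -0.43), camera adjusted p = 2.04e-15 and adjusted p = 0.241 with an estimated correlation. Adjusted over the list alone 11 members passed against 0 over all genes, and fry gave 0.156 one way and 0.0491 in either direction. LHCA4 was at -1.26 (SE 0.36) and LHCB3 at -1.45 (SE 0.51). In local leaves the same list had a median of 0.03, which was negative under upper-quartile factors (-0.04) and total counts alone (-0.16), with 16 of 29 members positive, LHCB3 at -1.05 and the Rubisco small subunits RBCS1B and RBCS2B at 0.98 (SE 0.26) and 0.73 (SE 0.28). That local median lay at percentile 0.26 of the random lists matched on expression, below nearly all of them. Camera's direction for the list in local leaves was up (adjusted p = 0.487). Plastid ribosomal proteins (-0.31, 16 of 16 negative, adjusted p = 6.24e-06; 0.614 estimated; PRPS20 -0.49), plastid-encoded genes (-0.34, 60 of 74, 0.000132; 0.65 estimated) and mitochondrial-encoded genes (-1.02, 62 of 63, 4.1e-18; 0.614 estimated) fell as well. The organelle-encoded transcripts are few in mRNA-selected libraries: mitochondrial genes took 0.0168% to 0.0972% of the counts.

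Among hormone and stress lists in systemic leaves, salicylic acid and systemic acquired resistance fell (median -0.86, 21 of 23 negative, adjusted p = 0.000106; adjusted p = 0.614 with an estimated correlation), but FMO1 (log2 -4.95), ALD1 (-3.41) and PR1 (-2.36), which act in or report on pipecolic acid and salicylic acid defence, turned to 2.88, 2.39 and 0.45 without control systemic library 1. Abscisic acid and dehydration fell (-0.86, 16 of 21; 0.0129; 0.637 estimated), with the cold and drought proteins COR15A at -2.02 and KIN2 at -1.75 (SE 0.66). Endoplasmic reticulum stress fell (-0.66, 10 of 12; 0.000392; 0.637 estimated), with the co-chaperone ATERDJ3B at -0.98, and heat shock fell (-0.48, 12 of 14; 0.0338; 0.65 estimated), with HSP17.6II at -3.80 on 5 reads in the Dox group. Cytokinin response rose (0.78, 7 of 7; 1.89e-05; 0.412 estimated), where ARR15 was at 2.66 (SE 0.95) and RR5 at 1.44, and so did auxin response (0.45, 9 of 14; 0.0344; 0.673 estimated), with IAA5 at 2.78 and the auxin-conjugating enzyme DFL1 at 2.39 (SE 0.75), and touch and cold-induced genes (0.20, 6 of 10; 0.0337; 0.65 estimated), with the cold regulator CBF1 at 1.61 (SE 0.44). Flower markers rose (1.86, 3 of 3 measured of 8; 0.0498; 0.412 estimated): SEP3 was at 2.11 and SEP1 (AT5G15800) at 1.86, at 8.86 ± 5.99 and 4.96 ± 4.17 CPM in the Dox group against 2.05 ± 0.154 and 1.38 ± 1.63. PYK10, the single root marker measured, was at -1.82 (SE 0.92), and KNAT6, the single shoot apex marker, at 0.69.

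Without control systemic library 1 the systemic medians were 0.94 for auxin response, 0.47 for cytokinin response, -0.31 for heat shock, -0.11 for plastid-encoded genes, -0.20 for salicylic acid and systemic acquired resistance and 0.07 for touch and cold. Without control systemic library 2 auxin response stood at 0.29, heat shock at -0.96 and touch and cold at -0.10. Without control systemic library 3 abscisic acid and dehydration stood at -0.54, auxin response at 0.04, cytokinin response at 1.2 and touch and cold at 0.84. Without Dox systemic library 1, at the auxin end of the first component, auxin response turned to -0.62, plastid ribosomal proteins stood at -0.21, plastid-encoded genes at -0.19 and touch and cold at 0.34. Without Dox systemic library 2 auxin response stood at 0.81, cytokinin response at 0.46 and heat shock at -0.99. Without Dox systemic library 3 abscisic acid and dehydration stood at -0.56, auxin response at 0.71, flower markers at 1.04 and touch and cold at 0.05. When camera ran on log2 CPM, auxin response (adjusted p = 0.0643), heat shock (0.115) and flower markers (0.115) were not called. The mitochondrial stress, photosynthesis, endoplasmic reticulum and mitochondrial-encoded medians moved by less than 1.5 times without any of the 6 libraries.

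The other lists did not pass in systemic leaves. Their medians were -0.15 for jasmonate (with LOX2, which begins jasmonate synthesis, at -1.75), -0.05 for ethylene (ERF5 1.27, SE 0.35), 0.13 for reactive oxygen response (the iron store FER1 1.45), 0.04 for cytosolic ribosomal proteins, -0.23 for senescence, -0.57 for iron deficiency (BHLH100 -1.91, which stood at -0.25 without control systemic library 2), 0.36 for anthocyanin and flavonoid, -0.63 for camalexin and indole glucosinolate, -0.64 for aliphatic glucosinolate, 0.05 for cell division, -0.38 for circadian clock, -0.32 for phase change, 0.57 for guard cell and stomatal lineage markers, 0.15 for vascular markers and 0.07 for reference genes. Fry in either direction called senescence and circadian clock, each at an adjusted p = 0.0491. In 3 of these, ethylene, cell division and reference genes, the median, the mean and camera's direction differed in sign, as they did for aliphatic glucosinolate and circadian clock in local leaves.

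**Figure D2:**
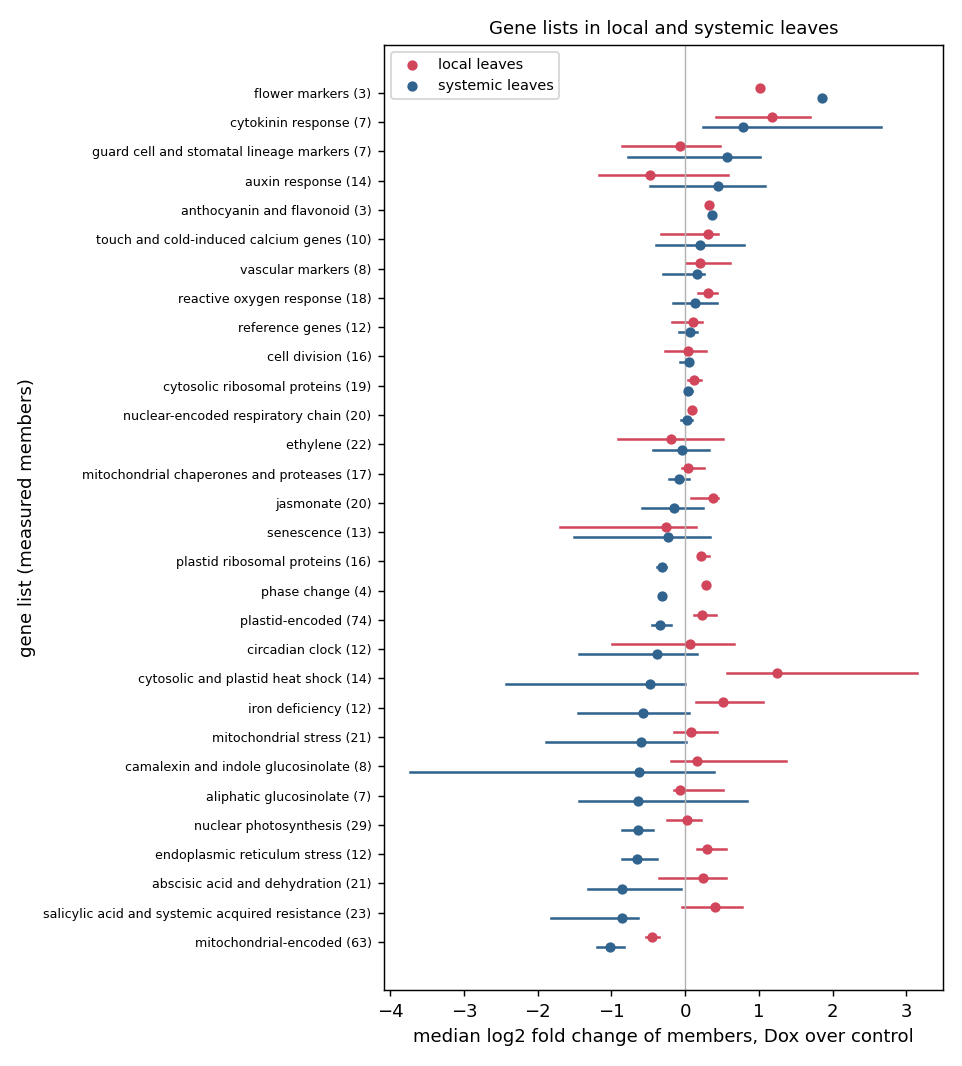
Median log2 fold change of each gene list in the local Dox and systemic Dox comparisons, with 95% intervals over members where drawn. Nuclear photosynthesis lies at 0.03 in local and -0.64 in systemic leaves, and the mitochondrial stress list at 0.07 and -0.60.

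**Figure D3:**
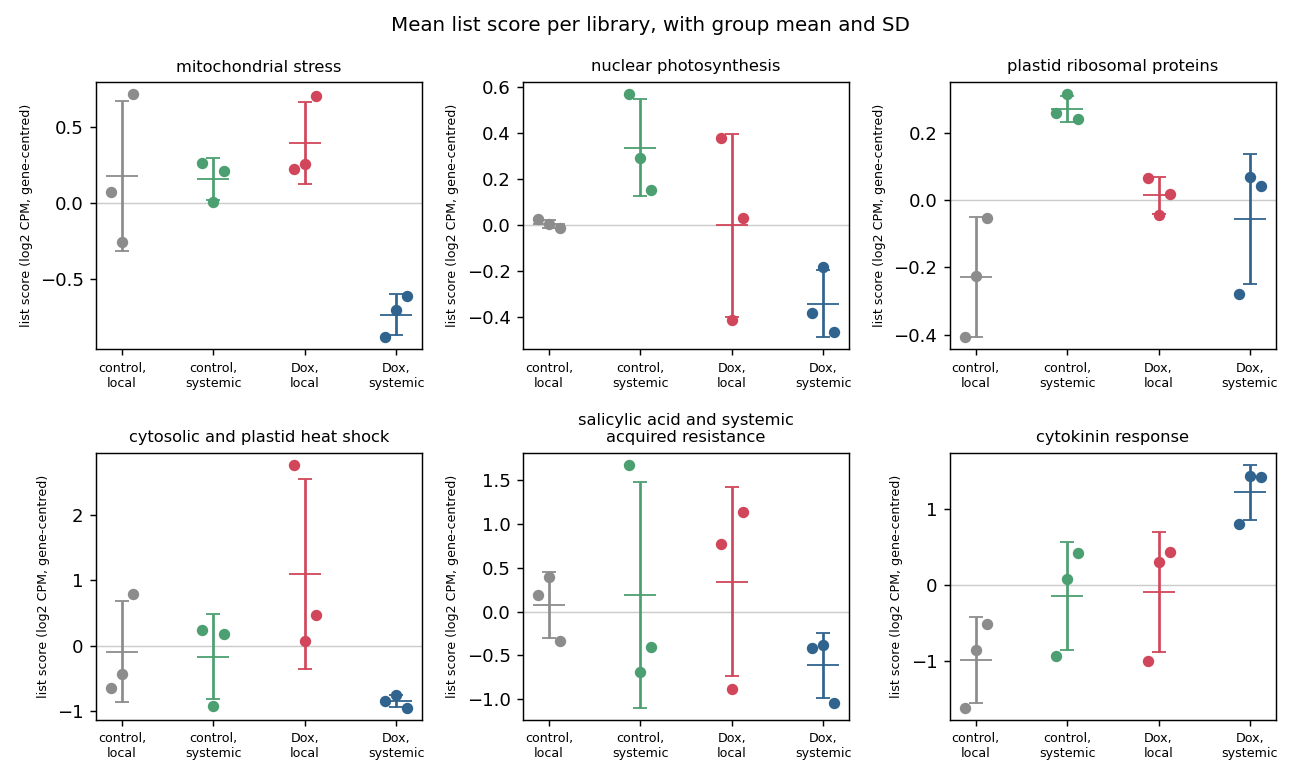
Scores of 6 gene lists (mean gene-centred log2 CPM of members) in each of the 12 libraries, by group, with the group mean and SD. The mitochondrial stress score of the Dox systemic libraries lies at -0.734 ± 0.136, and the lowest score of any other library is -0.257.

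Systemic leaves of control plants were compared with local leaves of the same plants to show how the leaves differed without Dox. The local leaves had been given water and the labels give no treatment for the systemic leaves, so leaf position and the application of water were not parted. Genes for proteins of the plastid ribosome were higher in systemic leaves in all 16 measured cases (median 0.51, 95% interval over members 0.37 to 0.54). Their camera adjusted p was 3.5e-14, and 0.501 with an estimated correlation. Among them were PRPL28 at log2 0.74 (SE 0.17, 79.4 ± 9.32 against 47.5 ± 10.9 CPM), EMB3136 at 0.61 (SE 0.15) and GHS1 at 0.61 (SE 0.17). Cytosolic ribosomal proteins (0.38, 19 of 19, 5.86e-10; PFL 0.71, SE 0.21), nuclear photosynthesis (0.33, 28 of 29, 1.86e-05; RBCS1B 0.81, SE 0.26), cell division (0.43, 14 of 16, 0.000248), cytokinin response (1.00, 7 of 7, 0.00363) and plastid-encoded genes (0.21, 54 of 74, 0.0379) also rose. Mitochondrial-encoded genes (-0.75, 62 of 63, 8.08e-11), touch and cold-induced genes (-0.63, 9 of 10, 0.000109; CBF2 -2.09, SE 0.42), abscisic acid and dehydration (-0.50, 17 of 21, 0.0027), reactive oxygen response (-0.45, 14 of 18, 0.00541), aliphatic glucosinolate (-0.60, 7 of 7, 0.0101), ethylene (-0.19, 18 of 22, 0.0171), jasmonate (-0.41, 17 of 20, 0.0186) and camalexin and indole glucosinolate (-0.32, 5 of 8, 0.0379; MYB51 -1.18, SE 0.35) fell. With an estimated correlation the adjusted p was 0.501 to 0.736 for these 14. When camera ran on log2 CPM, camalexin and indole glucosinolate (0.0618) and plastid-encoded genes (0.0645) were not called. Fry called plastid ribosomal proteins (0.0495), of which 13 members passed adjusted over the list alone. Genes in this and the following comparison were chosen after their values were seen.

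Gene by gene, edgeR called 0 of 19403 between leaf positions of control plants (smallest adjusted p 0.0707; 1334 at an unadjusted p under 0.05), and DESeq2 33 higher and 3 lower. Groups did not overlap for 13% of genes against 10% by chance. With library number as a block over the 6 libraries, the pairing described above, 71 of 18776 genes passed (45 higher and 26 lower in systemic leaves), 36 did when the trend with transcript length was removed as well, of which 32 were among the 71, and 12 plastid ribosomal protein members passed adjusted over the list alone. Plastid-encoded genes (0.20) lost their camera call with the block, and auxin response (0.37) gained one. In that fit the pectin methylesterase PME5 was at 1.84 (SE 0.17), OXS3 at 2.03 and the response regulator ARR7 at 1.35, while the cold and drought regulators CBF2 (-2.19) and DREB2A (-1.08) and the cell wall enzyme XTH19 (-1.49) fell (adjusted p = 0.0423 for PME5). Leaving out pair 1 or pair 3 ended all calls (0 genes by edgeR), and leaving out pair 2 gave 450. The signal recognition particle RNA AT7SL-1 was at 1.97 without the block. On summed counts 372 genes were at least 2-fold higher and 252 at least 2-fold lower of 18033; without control local library 2 these were 589 and 506, and the lower count was 446 without control local library 1 and 413, 121 and 933 without control systemic libraries 1, 2 and 3.

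Leaving out control local library 1, the position medians among control plants were -0.66 for jasmonate and 0.05 for plastid-encoded genes. Leaving out control local library 2, they were -0.58 for camalexin and indole glucosinolate, 0.84 for cell division, 0.09 for plastid-encoded genes and -0.79 for reactive oxygen response. Leaving out control local library 3, jasmonate turned to 0.12 and camalexin and indole glucosinolate to 0.06, abscisic acid and dehydration stood at -0.10, cell division at 0.28, ethylene at -0.28, mitochondrial-encoded genes at -0.07, plastid-encoded genes at 0.46, reactive oxygen response at -0.15 and touch and cold at -0.26, and 9 lists passed. Leaving out control systemic library 1, plastid-encoded genes turned to -0.07, with abscisic acid and dehydration at -0.33, camalexin at -0.97, ethylene at -0.54 and photosynthesis at 0.19. Leaving out control systemic library 2, camalexin turned to 0.06, with abscisic acid and dehydration at -0.22, ethylene at -0.01, jasmonate at -0.10, mitochondrial-encoded genes at -0.45, reactive oxygen response at -0.21 and touch and cold at -0.22. Leaving out control systemic library 3, aliphatic glucosinolate stood at -1.0, camalexin at -0.86, jasmonate at -0.92, reactive oxygen response at -1.01 and touch and cold at -1.16. Plastid and cytosolic ribosomal proteins and cytokinin response moved by less than 1.5 times throughout.

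Systemic and local leaves were also compared among Dox plants, a comparison added after the data had been seen. Heat shock genes were lower in systemic leaves (median -2.97, 13 of 14 members negative, 9 passing adjusted over the list alone; camera, adjusted p = 1.14e-05; adjusted p = 0.406 with an estimated correlation), with HSP70 at log2 -5.20 (SE 1.24; 3.55 ± 0.0527 against 131 ± 182 CPM) and HSP90.1 at -3.52 (SE 0.91). Without Dox local library 1 these stood at -2.87 and -1.85, and the list at -1.76. Iron deficiency genes fell (-1.51, 11 of 12, 7 over the list alone; 1.37e-05; 0.406 estimated), with AT1G47395 at -1.99 (SE 0.56) and the iron sensor BTS at -1.38 (SE 0.38; 153 ± 3.26 against 397 ± 94.9 CPM). The mitochondrial stress list fell (-1.11, 18 of 21, 8 over the list alone; 5.47e-06; 0.295 estimated), with AT5G51440 at -4.74 (SE 1.38) and the import subunit gene TIM17-1 at -1.85 (SE 0.44). Mitochondrial-encoded genes were lower in 63 of 63 cases (-1.32; 2.19e-20; 0.406 estimated). Auxin response rose (1.67, 13 of 14; 0.000791; 0.448 estimated), IAA29 being at 2.97 (SE 1.52; 1.85 without Dox systemic library 1 and 4.76 without Dox local library 2), and so did cytokinin response (0.80, 7 of 7; 0.00232; 0.406 estimated), guard cell and stomatal lineage markers (0.68, 7 of 7; 0.00193; 0.406 estimated; SPCH 2.63, SE 1.10, and 4.09 without Dox local library 2), cytosolic ribosomal proteins (0.25, 19 of 19; 0.000294; 0.448 estimated) and cell division (0.34, 15 of 16; 0.0275; 0.532 estimated).

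In the same comparison 10 further lists fell: salicylic acid and systemic acquired resistance (median -1.08), jasmonate (-0.84), abscisic acid and dehydration (-1.09, with HAI1 at -3.29, SE 1.08), endoplasmic reticulum stress (-0.96, with BIP2 at -1.56), reactive oxygen response (-0.92), photosynthesis (-0.42), camalexin and indole glucosinolate (-1.26, with CYP81F2 at -1.93, SE 0.61), aliphatic glucosinolate (-1.42, with CYP79F1 at -2.42, SE 0.74, and -1.22 without Dox local library 3), circadian clock (-0.59) and plastid-encoded genes (-0.38). With an estimated correlation their adjusted p was 0.406 to 0.551. Across all lists 53 members passed adjusted over the list alone. By edgeR 1 gene passed over all 19403, CRK4 (AT3G45860), a receptor-like kinase, at -1.66 (SE 0.17, adjusted p = 0.0123; 86.6 ± 8.27 against 274 ± 39.8 CPM); 3480 (17.9%) had an unadjusted p under 0.05, DESeq2 called 195 higher and 359 lower, and groups did not overlap for 23.7% of genes against 10% by chance. No gene passed by edgeR without Dox systemic library 1, 2 or 3 (0 each), and 13 did without Dox local library 2, which also moved cytokinin response to 1.39 and guard cell markers to 1.08. Leaving out Dox local library 1, cytokinin response stood at 0.49, heat shock at -1.76, jasmonate at -0.52, photosynthesis at -0.16, plastid-encoded genes at -0.17 and reactive oxygen response at -0.61. Leaving out Dox local library 3, circadian clock stood at -0.25. Without Dox systemic library 1 auxin response stood at 0.74, cell division at 0.16 and jasmonate at -0.54, and without Dox systemic library 3 cytosolic ribosomal proteins stood at 0.16 and jasmonate at -1.86.

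The Dox differences of the 2 leaf positions were then set side by side. Cytokinin response and the response regulator RR16 were higher in both (RR16 log2 1.67 and 2.63), and ASN1 was lower in both (-1.70 and -1.51). Of 17739 genes at 1 CPM or more in both comparisons, 36 were at least 2-fold higher and 73 at least 2-fold lower in both, where independent lists of those sizes would share 5.07 and 10.2, and 66 moved in opposite directions against 14.9. The 2 comparisons share no library, but those figures for independent lists leave out any likeness between leaves of the same plants. Moves in opposite directions exceeded their figure too, so the excess is not particular to a shared direction. The shared counts are therefore no measure of a common Dox response. Across genes, which are not independent replicates, the log2 ratios had Pearson r = 0.0745 and Spearman rho = 0.0503. The shared count of 109 became 64 without control local library 1 or control systemic library 1 and 170 without Dox local library 3. The correlation turned negative without control local library 3 (-0.0379), control systemic library 1 (-0.0475) or 2 (-0.0083), Dox local library 2 (-0.0555) or Dox systemic library 3 (-0.0549). It was 0.0476 without control local library 1, 0.214 without control local library 2, 0.286 without control systemic library 3, 0.123 and 0.204 without Dox local libraries 1 and 3 and 0.181 without Dox systemic library 1. In the test of a Dox difference common to both positions, edgeR called 0 genes (smallest adjusted p 0.399; 1608 at an unadjusted p under 0.05), 2 without Dox local library 1, and DESeq2 46 higher and 56 lower. The same model called 1 gene for leaf position, AT7SL-1 (1.6, SE 0.19, adjusted p = 0.0387). This model takes all libraries as independent, although local and systemic leaves came from the same sets of plants, so its p-values may be too small for Dox.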

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

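The one-library tests below, the interaction itself and the clock covariate on mitochondrial stress genes were chosen after the results had been seen. The tests on transcript length were not, except for the block by library number used for plastid ribosomal proteins. That block rests on a pairing accepted from these data. The other tests with the dehydration-to-auxin state or the clock score as a covariate were set before their outcome was known, on scores whose values had been seen. The difference between the local and the systemic Dox effect (local minus systemic) was past camera's threshold at its preset correlation for 11 lists, and that difference is what brought them here. By edgeR 0 genes passed for it (1008 at an unadjusted p under 0.05; DESeq2 was not run on it), and with an estimated correlation the smallest adjusted p was 0.426, so no call held. When camera ran on log2 CPM, abscisic acid and dehydration (0.135) and auxin response (0.0572) were not called.

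Mitochondrial stress genes had a median difference of 0.88 (local 0.07, systemic -0.60; camera adjusted p = 4.93e-05, 0.426 with an estimated correlation). Salicylic acid and systemic acquired resistance differed by 1.26 (0.40 and -0.86; 9.07e-05, 0.73 estimated). Abscisic acid and dehydration differed by 0.47 (0.25 and -0.86; 0.0405, 0.751 estimated). Auxin response differed by -0.97 (-0.48 and 0.45; 0.0149, 0.751 estimated). Heat shock differed by 2.68 (1.25 and -0.48; 7.97e-07, 0.476 estimated). Endoplasmic reticulum stress differed by 0.84 (0.30 and -0.66; 0.00013, 0.73 estimated). Nuclear photosynthesis differed by 0.71 (0.03 and -0.64; 1.02e-11, 0.426 estimated). Plastid ribosomal proteins differed by 0.55 (0.21 and -0.31; 1.42e-10, 0.476 estimated). Iron deficiency differed by 1.39 (0.51 and -0.57; 0.000331, 0.73 estimated). Mitochondrial-encoded genes differed by 0.56 (-0.45 and -1.02; 6.78e-06, 0.751 estimated) and plastid-encoded genes by 0.63 (0.23 and -0.34; 1.71e-07, 0.73 estimated).

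Single libraries moved several of these differences. Leaving out Dox local library 1, heat shock stood at 0.83, and without control local library 3 at 4.08, with abscisic acid and dehydration at 0.99 and mitochondrial-encoded genes at 1.36. Without Dox systemic library 1 auxin response turned to 0.05 and mitochondrial-encoded genes stood at 0.36. Without control systemic library 1 auxin response stood at -1.47, plastid-encoded genes at 0.35 and salicylic acid and systemic acquired resistance at 0.43. Without control systemic library 2 iron deficiency stood at 0.42 and mitochondrial-encoded genes at 0.84, and without control systemic library 3 abscisic acid and dehydration stood at 0.21. Without Dox local library 2 abscisic acid and dehydration stood at 0.72 and auxin response at -1.48, and 17 lists passed. Without Dox local library 3 abscisic acid and dehydration stood at 0.18 and mitochondrial stress at 0.57. Without control local library 1 mitochondrial-encoded genes stood at 0.33, without control local library 2 at 0.29 with abscisic acid and dehydration at 0.31 and auxin response at -0.51, and without Dox systemic library 2 at 0.85. Of 60 splits of the 12 libraries drawn within leaf positions, 28 gave at least as many lists (real 11, highest other 17), and 19 as many genes at an unadjusted p under 0.05 (real 1008, highest other 3814), so chance cannot be excluded for either. The count of genes past the threshold says nothing here, since all 60 splits reach a real count of 0 (highest other 59).

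Mitochondrial stress genes, AOX1D and DTX1 among them, lay lower in systemic leaves of Dox plants than in those of control plants. With the dehydration-to-auxin state of the libraries as a covariate the list score still differed by -0.745 (SE 0.218), against -0.895 (SE 0.243) without it. The covariate is made of list scores alone, and the list member AT5G51440 is among the leading genes of the first component. It therefore cannot exclude that state as an explanation. Removing the trend with transcript length left the list median at -0.60 (-0.5999), and the highest median without any 1 library was -0.55 (-0.5467), so neither length nor 1 library accounts for it. Whether the libraries of a group came from separate plants, and the hour of harvest, stay open; with the clock genes as a covariate the score differed by -1.055 (SE 0.419). A lower mitochondrial stress state in systemic leaves of treated plants is a hypothesis that these libraries may reflect, found and tested on the same data.

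Nuclear photosynthesis genes, the light-harvesting LHCB2.1 and LHCB6 among them, also lay lower in systemic leaves of Dox plants. Removing the length trend left the median at -0.6324 and the highest median without 1 library was -0.5059, so neither accounts for it. The hour of harvest stays open: with a clock gene score as a covariate the list score differed by -0.241 (SE 0.266) against -0.678 (SE 0.193) without it, the SE growing because the score separates all Dox from all control libraries. Local leaves had that shift in clock genes too, with a photosynthesis median of 0.03. That median lay at percentile 0.26 of the random lists matched on expression, while camera's direction for the list was up (adjusted p = 0.487). Lists that did not pass in local leaves reached such percentiles too (auxin response 0.01, jasmonate 99.99). The percentile therefore does not show that photosynthesis genes fell there. A different hour of harvest, or an effect of Dox on clock genes, may underlie part or all of the difference; these libraries do not part them, and the clock genes were picked after their values had been seen.

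Plastid ribosomal protein genes, PRPL28 and EMB3136 among them, lay higher in systemic than in local leaves of control plants. The log2 fold changes of this comparison correlated with transcript length (Spearman rho -0.307). Of the systemic libraries, number 1 stood apart in this (rho of its levels -0.341, against 0.0226 and -0.0488). The local libraries were at 0.208, 0.153 and 0.0825. Yet with the length trend removed the list median was still 0.3742 with library number as a block and 0.369 without the block. Before the removal these were 0.5205 and 0.5127, so length accounts for part of the difference at most. The lowest median without 1 library was 0.4211. Leaf position, leaf age and the water given to local leaves, which the design does not part, may account for the rest, and no test of them was run. A position or age difference that Dox left unchanged would be seen among Dox plants too. There the list scores were 0.014 ± 0.056 in local and -0.057 ± 0.194 in systemic leaves, against -0.228 ± 0.177 and 0.271 ± 0.038 in control plants. These values argue against such a difference, but not against one that Dox altered. The argument rests on the scores, as the interaction of this list did not hold with an estimated correlation (camera, adjusted p = 0.476). With the length trend removed the interaction median was 0.4925.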

How the results depend on the processing

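Every alternative in the fits with replicates, and each fit without 1 library, was chosen after the columns had been seen; those of the size counts on summed counts were planned, except leaving out libraries. Of 143 log2 fold changes of genes given in the text, each of 1 gene in 1 comparison, 142 kept their direction under every alternative other than leaving out 1 library, AOX1A in local leaves being the exception; of 2782 alternative values for them, 126 passed a threshold the first test did not. Of 126 list medians, 90 kept their sign under every such alternative and 36 did not; the 6 sign changes of lists that had passed, of which 1 was in a fit with all libraries and 5 with a pair of libraries left out, are all given below, and 42 of the 2408 values for all lists moved by more than the spread. Of 268 values of 19 counts, 214 stayed within 1.5 times. The cause of each change below was not tested, except where a fold, a filter or fewer samples makes it.

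With total counts alone 183 genes were at least 2-fold higher in local leaves, AOX1A there stood at -0.0387 with the median of all genes at -0.119, and edgeR called 1 gene between positions of control plants and 0 of Dox plants. With no filter beyond 1 read the size counts were 1290 higher and 1261 lower in local leaves, 1226 and 1495 in systemic leaves and 1282 and 1061 between control positions, with 410 shared, and edgeR called 1 gene between control positions. With a 5 CPM filter they were 168 and 172, 200 and 370, and 130 and 162, with 49 shared, and the systemic mitochondrial stress median was -0.4443. At 4-fold they were 42 and 51, 56 and 120, and 54 and 9, with 6 shared, and at 1.5-fold 1338 and 1027, 1295 and 1546, and 1171 and 1074, with 507 shared. Upper-quartile factors gave 1 gene between control positions.

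DESeq2 called 14 genes in local leaves, 122 in systemic leaves, 36 between control positions, 554 between Dox positions and 102 for the common Dox difference, and over the 6 libraries compared 16, 315, 43 and 1442 for the first 4. Voom with library quality weights turned the local mitochondrial-encoded median to 0.0562 and gave 1 gene between control positions. The fit over the 6 libraries compared gave 0 genes between Dox positions. Library number as a block over 12 libraries gave 2 there; over 6 libraries it gave 2 in systemic leaves, 71 between control positions and 0 between Dox positions. With the length trend removed as well the control count was 36, and with DESeq2 and the block 876. In that block, leaving out pair 1 turned the plastid-encoded median to -0.2081, and leaving out pair 2 gave 450 genes and an ethylene median of 0.1008. With the length trend removed the list calls of camera on counts were as before in local and systemic leaves, between Dox positions and for the interaction (7, 13, 19 and 11 lists), and between control positions guard cell markers (median 0.0699, adjusted p = 0.043) joined the 14. On log2 CPM guard cell markers were not called (camera, adjusted p = 0.0808). There the removal ended the calls of cytosolic ribosomal proteins in local leaves (0.218) and of cell division (0.0546) and circadian clock (0.0664) between Dox positions. It added auxin response in systemic leaves (0.0468) and for the interaction (0.032), and plastid-encoded genes between control positions (0.0417). Without control local library 3 and Dox local library 1 together, 12 lists passed in local leaves, where the mitochondrial-encoded median was 0.3132, and 9 between control positions, with jasmonate at 0.1074 and camalexin and indole glucosinolate at 0.0477, and 0 genes passed between Dox positions.

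Leaving out 1 library at a time, the size counts ran from 218 to 1051 higher and 250 to 637 lower in local leaves, 323 to 642 and 567 to 936 in systemic leaves, and 372 to 589 and 121 to 933 between control positions, with 64 to 170 shared and a correlation of -0.0555 to 0.2859. Lists past the threshold ran from 4 to 13 in local leaves, 9 to 15 in systemic leaves, 9 to 16 between control positions, 18 to 19 between Dox positions and 9 to 17 for the interaction. The mitochondrial stress median ran from -0.0719 to 0.5467 in local and -0.8893 to -0.5467 in systemic leaves. Genes called ran from 0 to 13 between Dox positions and 0 to 2 for the common Dox difference, and stayed at 0 by edgeR in the others. In local leaves the mitochondrial-encoded median ran from -0.7555 to 0.2205, HSFA2 from -0.1366 to 8.044 and AOX1A from -0.2126 to 0.546. In systemic leaves auxin response ran from -0.6184 to 0.9403, touch and cold from -0.1042 to 0.8428, ARD3 from -5.0926 to 2.5604, AIG1 from -4.4675 to 0.6808, FMO1 from -6.1146 to 2.8785, ALD1 from -6.6787 to 2.3884, PR1 from -2.8861 to 0.4507 and bHLH39 from -1.8643 to 0.0936. Between control positions jasmonate ran from -0.9213 to 0.1153, camalexin and indole glucosinolate from -0.9742 to 0.058 and plastid-encoded genes from -0.0716 to 0.4552, and the auxin difference of the interaction from -1.4843 to 0.0491. Where 1 library is left out of 3, a spread pooled over groups stands in for the missing one.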

Other observations

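The relation between dehydration and auxin genes and the clock score were taken up after the values had been seen; the counts of other splits were set before their outcome was known, for tests that were added once the columns had been seen. Libraries of one group differed in a way that ran across all 4 groups. With group means removed, the scores of the abscisic acid and dehydration list and the auxin list had r = -0.737 and rho = -0.783 over 12 libraries. The lists were picked because genes of both kinds led the first component of the same libraries, so these values describe that component again and are no test of it. Without the libraries farthest from the median (Dox local libraries 1 and 2) r was -0.801. Control local library 3 and Dox local library 1 lay at the dehydration and heat shock end, and Dox systemic library 1 at the auxin end. A state that varied between leaves of one group, such as water status or handling at harvest, is a candidate explanation, and nothing in the sources used here records it.

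Part of the clock genes lay apart in Dox and control libraries. The mean of the morning genes CCA1 and LHY minus that of 6 genes that peak later in the day (TOC1, GI, LUX, ELF4, PRR5 and PRR7) lay between 0.239 and 2.264 in the 6 Dox libraries and between -2.064 and -0.025 in the 6 control libraries. These genes were picked after their values had been seen, so the mean difference of 2.124 has no test. The whole clock list of 12 measured members did not pass camera in local (median 0.065, adjusted p = 0.782) or systemic leaves (-0.3839, adjusted p = 0.0557), and 0 of 30 list scores parted Dox from control libraries. In systemic leaves LHY was at log2 2.54 (SE 0.82; 1.13 ± 0.645 against 0.182 ± 0.197 CPM), PRR5 at -1.44 and GI at -1.73.

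Between groups of 3 libraries the splits are too few (10) for a share under 0.05, and where the real count is 0 every split reaches it. In local leaves 10 splits gave as many genes (real 0, highest other 477) and 10 as many lists (7 and 13). Each other split gave 10 to 13 lists there, more than the real grouping. The number of lists called at camera's preset correlation therefore does not set Dox apart in local leaves. The split with 477 genes sets control local library 3 and Dox local libraries 1 and 3 against the others, which points to a structure of the samples along the first component. In systemic leaves 10 gave as many genes (0 and 0) and 5 as many lists (13 and 19). Between positions of control plants these were 10 (0 and 0) and 4 (14 and 18), and of Dox plants 1 (1 and 0) and 1 (19 and 17). At an unadjusted p under 0.05 the real count and the highest other were 915 and 4906 in local leaves, 1670 and 1135 in systemic leaves, 1334 and 2671 between control positions and 3480 and 1789 between Dox positions. These splits leave the pairing of control libraries aside. With library number as a block, 71 genes passed between control positions as labelled and 0 with pair 1, 2 or 3 swapped. The counts at an unadjusted p under 0.05 were 3214 as labelled and 652, 361 and 235 swapped. Such swaps are also too few for a share under 0.05, and the pairing came from the same data. For the Dox difference common to both positions, all 60 drawn splits reach the real count of 0 genes (highest other 358), which says nothing. At an unadjusted p under 0.05, 9 of the 60 gave as many genes (real 1608, highest other 4594), so chance cannot be excluded.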
